A study of Mus musculus with 23 samples.

How the data were processed

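Gene expression was measured in gastrocnemius muscle of male C57BL/6J mice on 1-colour Agilent arrays, per the labels. The 23 arrays fall into 6 groups, adult or old mice kept sedentary, trained by high-intensity intermittent training (HIIT) or trained by moderate-intensity continuous training (MICT). The labels name liver only in the title, and only muscle was analysed here. The labels give 4 mice per group, and adult MICT has 3 arrays, with replicate 2 absent.

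Per the file headers, Agilent Feature Extraction made the deposited intensity values of each array separately: the processed signal was background subtracted and detrended within the array, and low values were replaced by a surrogate. It was not scaled between arrays, per the file headers. The deposited raw median intensity of each spot and of its local background, and the software's flags for each spot, were also used. A deposited series file holds a score per spot. How that score was made is not stated, and on every array it followed the log10 processed signal with r of at least 0.99954 and a median between -0.4 and -0.2, which is what a z-score of the log10 signal within each array, rounded to 1 decimal, would give.

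Each array held 62976 spots, of which 3671 were controls and were left out, leaving 59305 spots of 55681 probes. Spots that the software marked as non-uniform or as population outliers were left out, 283 probes with every spot so marked on at least 1 array were dropped, and spots of a probe were averaged on the log2 scale. The log2 intensity computed from the deposited signal was scaled by subtracting each array's 75th percentile, so that a value of 0 stands for that percentile. A probe was tested if the software called it well above background on at least 3 arrays, which left 31942 probes. The files give no gene name, so symbols were matched by accession to a RefSeq table of the GRCm38.p6 assembly, used for names only because the array's own annotation is of mm9. Of 29786 RefSeq accession probes, 28331 matched. Where several tested probes shared a symbol, the probe with the highest mean signal was used, and probes without a symbol stayed as features of their own. This gave 23708 features, 15466 of them with a symbol.

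Differences were tested with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table), with 6 group means fitted to all 23 arrays, a moderated variance with an intensity trend, 2-sided tests and Benjamini-Hochberg adjustment over the 23708 features of each comparison. A feature was called at an adjusted p under 0.05. The 9 comparisons were each training regimen against its control at each age, old against adult controls, HIIT against MICT at each age, and the 2 differences in training response between ages. Each value after ± is limma's standard error (SE) of a log2 difference unless called an SD. Where no array of a group had a probe above background, the fold is given as a lower bound, computed with each array of that group set to at least its lowest signal called above background.

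The 32 lists, 21 of pathways and states and 11 of cell type markers, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and limma's fry were alternatives. Fry asks whether a list's genes move one way on balance, and does not set them against other genes. An array's score for a list is the median over its genes of the deviation from the adult control mean, in log2 units, and scores of groups were compared with exact 2-sided permutation tests, for which 4 arrays against 4 allow no p below 0.0286.

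The lists, the tests, the design and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the genes with the largest rise and fall among called genes whose groups did not overlap, the members with the smallest p of lists that were called or held called genes, and a fixed set of muscle and exercise genes. Where fewer than 5 genes were called, it also took those with the smallest unadjusted p. One gene taken by the rule is not reported here. Genes outside this rule carry a statement that they were chosen after their values were seen.

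Alternatives were another background correction (normexp with an offset of 50, run on median signals because the files hold no mean signal), quantile or z-score scaling, other filters and variance models, array weights, a replicate block, an additive model with slide, all probes, the deposited value table, a fold of at least 1.5, fits of the compared groups alone, and each array left out in turn. Sets of arrays left out, covariates for cell composition and the exact test of list scores were added after the data had been seen. The composition covariates were the lymphocyte (mean of the B and plasma cell and the T and NK cell score), adipocyte and slow-twitch fibre scores. Comparisons that share controls were set beside 100 simulated draws of unchanged groups and beside splits of the controls.

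The method was tested on simulated data built from these arrays with 200 changed genes among 23708. For MICT against control in old mice it recovered 9% of genes changed 1.5-fold, 56% of those changed 2-fold and 83% of those changed 4-fold. For MICT against control in adult mice the shares were 11.5%, 40.5% and 85.5%. The simulation drew noise independently for each gene, with the same SD in all groups. It held no correlation between genes and no differences in cell composition between arrays. It also changed far fewer genes than were called in old MICT, so these shares may not hold for the real data. The 75th percentile of the signal ran from 262 to 656 between arrays, and 47.2% to 58.9% of gene spots were well above background. The number of arrays limits the precision.

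The arrays lay on 3 slides, per the file headers. Slide 1 held adult control and adult HIIT, slide 2 held adult MICT and old control, and slide 3 held old HIIT and old MICT, with the replicate number equal to the position in a row. Slide and group cannot be told apart where the groups compared lie on different slides. Adult HIIT against its control and old HIIT against old MICT are comparisons within a slide. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.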

Results

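The series asked how muscle of adult and old male mice responds to a pair of treadmill regimens. Mice began at 5 months (adult) or 24 months (old) and trained daily for 4 weeks. HIIT was 3 runs of 2 min at 27 m/min, with 1 min at 5 m/min between them, and MICT was a single run of 45 min at 13 m/min. Sedentary controls were placed on a stopped treadmill. Gastrocnemius, a mostly fast-twitch calf muscle, was taken after 12 h of rest, and 200 ng of RNA was labelled per array. There were 4 arrays of adult controls, 4 of adult HIIT, 3 of adult MICT, 4 of old controls, 4 of old HIIT and 4 of old MICT. Between arrays, 47.2% to 58.9% of gene spots were well above background.

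Transcripts of non-muscle cells differed between arrays of the same group. The B and plasma cell score was 5.56 and 4.00 in old controls 1 and 2, 1.88 and 1.40 in old controls 3 and 4, 4.15 in old HIIT 2, and between -0.15 and 0.12 in the 4 adult controls. The T and NK cell score was 3.65 and 3.09 in old controls 1 and 2. The neutrophil and mast cell score was 5.50 in old control 4 and 4.01 in old HIIT 1. The cell cycle score was 3.78 in old control 4, against 1.07 to 1.23 in the other old controls. Adipocyte scores also varied in adult mice, at 3.04 in adult HIIT 3 and 2.23 in adult MICT 1 and 3. Slow-twitch fibre scores ran from -0.68 to 1.44 among adult controls and from -1.86 to 1.07 in adult MICT.

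**Figure D1:**
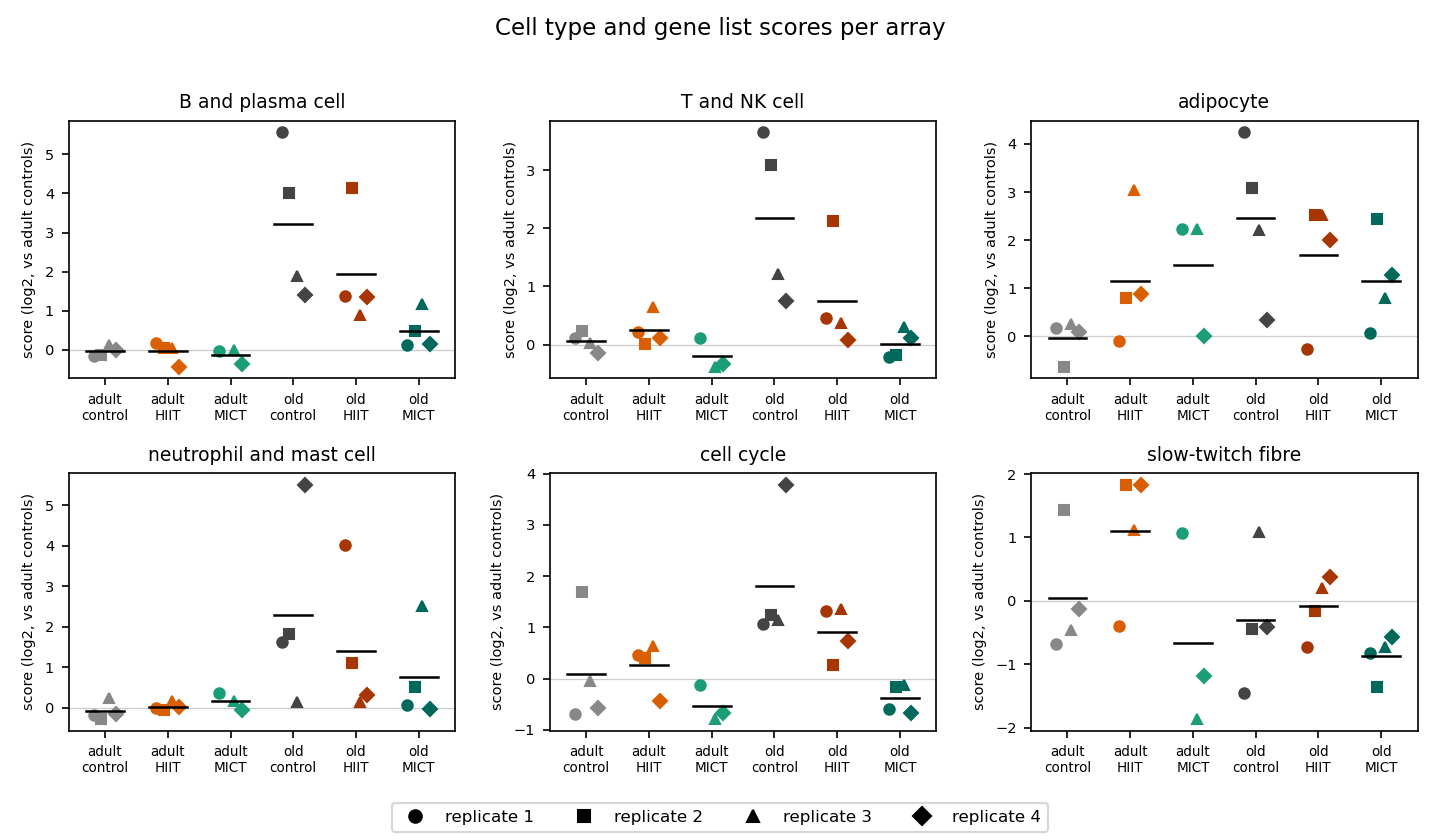
Scores of 6 gene lists per array (vertical axes, log2 units, median over the list of the deviation from the adult control mean), with arrays grouped by age and training, markers giving the replicate number and bars giving group means. Old controls 1 and 2 have B and plasma cell scores of 5.56 and 4.00, and old control 4 has a cell cycle score of 3.78.

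Part of the lymphocyte, adipocyte and cell cycle genes were called higher in old than in adult sedentary samples, and part of the mitochondrial enzyme genes were called lower. With an estimated correlation, no such list was called. Fry called the T and NK cell (fry adjusted p = 0.00602), B and plasma cell (0.00602), cell cycle (0.0284), adipocyte (0.0492) and tricarboxylic acid cycle (0.0492) lists. It did not call the respiratory chain list (0.0717), and it does not set a list against other genes. Ms4a1, which encodes a B-cell surface protein, was higher by 5.73 ± 1.02 log2 units (n = 4 and 4, limma adjusted p = 0.00564), at least 22.8-fold. Spib, a B-cell transcription factor, was higher by 5.43 ± 0.83, at least 15.5-fold. Of the 8 measured B and plasma cell genes, 6 rose over all genes tested and 8 rose adjusted over the list alone. Their median was 3.15 (camera adjusted p = 4.61e-09, adjusted p = 0.223 with an estimated correlation). The group means of that score were 3.21 ± 1.93 (SD, n = 4) and -0.04 ± 0.13 (SD, n = 4), with an exact 2-sided permutation p of 0.0286, the smallest possible, and 0.183 after adjustment over the 32 lists. Of 11 T and NK cell genes, 6 rose, and 6 rose adjusted over the list alone. They include Cd3g, part of the T-cell receptor complex (4.70 ± 0.92), and Gzmb, a protease of cytotoxic cells (3.97 ± 0.49, at least 4.31-fold). The T and NK median was 2.41, or 1.48 with undetected genes at their bound (adjusted p = 0.223 with an estimated correlation). The T and NK score was 3.65 and 3.09 in old controls 1 and 2 but 1.22 and 0.75 in old controls 3 and 4. Lymph node stroma genes, a list made after these rises were seen, moved with them, with a median of 2.45 over 4 genes and scores of 4.12, 3.46, 1.17 and 1.04 in old controls 1, 2, 3 and 4, so these transcripts need not come from within the muscle.

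Adipocyte genes moved with these lymphocyte genes. Of 10 measured, 4 rose over all genes and 10 rose adjusted over the list alone, with a median of 2.43 (adjusted p = 0.331 with an estimated correlation). Plin1, which coats lipid droplets, was higher by 2.95 ± 0.81 and Lep, the hormone leptin, by 3.66 ± 1.02. Of 19 cell cycle genes, 9 rose over all genes and 14 rose adjusted over the list alone (median 1.87, adjusted p = 0.275 with an estimated correlation). Mki67, a marker of dividing cells, was higher by 3.01 ± 0.72 (adjusted p = 0.0168), and the cell cycle score stood highest in old control 4. Ccl5, a chemokine that attracts T cells, rose by 4.12 ± 0.72, and Phgdh, the first enzyme of serine synthesis, by 2.06 ± 0.37. Lor, which encodes the skin protein loricrin, rose by 7.36 ± 2.24, with a between-array SD of 4.05 in old controls (adjusted p = 0.0372).

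Of 72 respiratory chain and ATP synthase genes, 13 fell with age over all genes and 31 fell adjusted over the list alone. Their median was -0.33 against -0.15 for all genes (camera adjusted p = 2.74e-08, adjusted p = 0.761 with an estimated correlation). Ndufa7, a subunit of complex I, fell by 0.41 ± 0.09 (adjusted p = 0.0112). Of 20 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 8 fell over all genes and 11 fell adjusted over the list alone (adjusted p = 0.682 with an estimated correlation). Suclg2, a subunit of succinyl-CoA ligase, fell by 0.64 ± 0.14 and Idh3g, a subunit of isocitrate dehydrogenase, fell by 0.59 ± 0.14. Of 16 fast-twitch fibre genes, 5 fell over all genes and 7 fell adjusted over the list alone (adjusted p = 0.796 with an estimated correlation). Among them, Atp2a1, the calcium pump of fast fibres, fell by 0.96 ± 0.24. Myh7, the slow myosin heavy chain, differed by -0.12 ± 0.87 (adjusted p = 0.938). The respiratory chain scores were -0.45, -0.55, 0.04 and -0.35 in old controls 1, 2, 3 and 4, whose lymphocyte scores (mean of the B and plasma cell and the T and NK cell score) were 4.60, 3.55, 1.55 and 1.08. Old control 4 had the highest neutrophil and mast cell (5.50), macrophage (1.32) and cell cycle (3.78) scores of all arrays.

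In the comparison by age, limma called 3235 of 23708 features, 1085 higher and 2150 lower in old controls. Without old controls 1 and 2, 24 were called (17 higher and 7 lower), 16 of them shared with the 3235; 40 were called when only these groups were fitted (28 and 12) and 15 with composition covariates (12 and 3, with 6 shared), so the majority of lower features did not hold there. These groups lie on different slides. Leaving out single arrays gave 674 (old control 1), 524 (old control 2), 5803 (old control 3), 510 (adult control 1, 266 higher and 244 lower), 718 (adult control 3) and 848 (adult control 4).

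HIIT in adult mice was tested against adult controls on the same slide. Slow-twitch fibre genes stood higher in adult HIIT, with a median of 1.08 over 16 genes (camera adjusted p = 4.98e-09, adjusted p = 0.737 with an estimated correlation). Tnni1, the slow troponin I, differed by 1.79 ± 0.89 (n = 4 and 4, adjusted p = 0.914) and Csrp3, a muscle stretch-sensing protein, by 1.60 ± 0.70 (adjusted p = 0.914). The slow-twitch score was 1.83, 1.12 and 1.82 in adult HIIT 2, 3 and 4, -0.39 in adult HIIT 1, and 1.44 in adult control 2. All 32 fatty acid uptake and oxidation genes were positive, with a median of 0.26 (camera adjusted p = 1.44e-06, adjusted p = 0.737 with an estimated correlation). Acsl1, which activates fatty acids, differed by 0.57 ± 0.20. Adipocyte genes stood higher in the same comparison, with all 10 positive and a median of 1.204 (camera adjusted p = 0.000112, adjusted p = 0.737 with an estimated correlation), as did 12 tendon genes, with a median of 0.48 (camera adjusted p = 0.00366, adjusted p = 0.737 with an estimated correlation). Ppargc1a, a regulator of mitochondrial biogenesis, differed by 0.36 ± 0.20 (adjusted p = 0.914). Abcb9, a lysosomal peptide transporter, differed by 0.52 ± 0.11 (adjusted p = 0.879). Limma called 0 features in adult HIIT, with 1215 at an unadjusted p under 0.05 and a smallest adjusted p of 0.434. Array weights gave 248 calls, and without adult HIIT 3 camera called 8 lists, against 13 with all arrays.

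MICT in adult mice was tested against adult controls on another slide. Adipocyte genes stood higher in adult MICT, with a median of 1.44 over 10 genes (camera adjusted p = 1.57e-08, adjusted p = 0.690 with an estimated correlation). Among these, Lep differed by 2.76 ± 1.11, Plin1 by 1.78 ± 0.88 and Adipoq, the fat hormone adiponectin, by 1.58 ± 0.82 (n = 3 and 4, limma adjusted p = 1 for each). The adipocyte score was 2.23 in adult MICT 1 and 3 and 0.00 in adult MICT 4. The cell cycle list lay lower, with a median of -0.41 over 19 genes (camera adjusted p = 0.00287, adjusted p = 0.964 with an estimated correlation). Its score was 1.68 in adult control 2 and -0.70, -0.05 and -0.57 in adult controls 1, 3 and 4, against -0.13, -0.79 and -0.68 in adult MICT, so adult control 2 carries most of the difference. The slow-twitch list also lay lower, with a median of -0.74 over 16 genes (camera adjusted p = 0.00513, adjusted p = 0.964 with an estimated correlation) and scores of 1.07, -1.86 and -1.18 in adult MICT 1, 3 and 4. Pdk4, which slows glucose oxidation, differed by 0.82 ± 0.82 and Ppargc1a by 0.12 ± 0.21. Limma called 0 features, with 500 at an unadjusted p under 0.05 and a smallest adjusted p of 0.955, and array weights gave 2 calls. Camera called 6 lists, but 12 without adult control 1, 3 without adult control 2 and 12 without adult MICT 1; limma's fry called 0 lists in adult HIIT and 0 in adult MICT.

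Weakly expressed features were higher in old HIIT than in old controls. Cyp2c67, a cytochrome P450 best known from liver, was higher by 2.89 ± 0.37 (n = 4 and 4, adjusted p = 0.00166), at least 3.76-fold. Gpr15, a lymphocyte homing receptor, was higher by 2.08 ± 0.36 (at least 2.47-fold) and Krt82, a hair keratin, by 2.00 ± 0.38 (at least 3-fold). The median mean signal of the called risers was -3.43 on the scaled log2 axis, against -0.45 for all features. Of these risers, 83 were also called lower in old than in adult controls, where independent lists would share 9.16. In old MICT, 99 were also called higher. Krt82, Gpr15 and Cyp2c67 were above background on 4, 3 and 2 adult control arrays and on no old control array. The old controls enter each of these comparisons, so a rise with HIIT was not told apart from a low signal in the old controls. Gzmb fell by 2.63 ± 0.49 (adjusted p = 0.0205). Genes of fuel use and protein breakdown had large differences that did not pass: Pdk4 2.70 ± 0.76 (adjusted p = 0.12), Fbxo32, a muscle ubiquitin ligase, 1.81 ± 0.62 (adjusted p = 0.195), and Trim63, another such ligase, 1.65 ± 0.64 (adjusted p = 0.24). Pdk4 was 8.68 and 7.39 in old HIIT 1 and 2 but 4.93 and 4.97 in old HIIT 3 and 4.

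Fatty acid genes as a list stood higher in old HIIT, with all 32 positive, a median of 0.47 and 0 called over all genes, 4 adjusted over the list alone (adjusted p = 0.567 with an estimated correlation). Interferon and antigen presentation genes stood lower, with all 34 negative and a median of -0.75 (camera adjusted p = 1.54e-12, adjusted p = 0.567 with an estimated correlation). The interferon scores of old controls 1 and 2 were 1.70 and 1.05, and these arrays had the highest lymphocyte scores. Limma called 103 features, 101 higher and 2 lower, of which 34 have a symbol. Of these groups on different slides, 0 features were called when they were fitted alone or with normexp background, 13 with composition covariates, 12 without old controls 1 and 2, and 5 without old control 4 and old HIIT 1. Single arrays left out gave 11 (old HIIT 1), 56 (old HIIT 3), 13 (old HIIT 4), 41, 27, 833 and 28 (old controls 1, 2, 3 and 4) and 159 (adult HIIT 3).

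In old MICT, most of the fatty acid and protein degradation genes were called higher than in old controls, which lie on another slide. Part of the extracellular matrix, cell cycle and lymphocyte genes were called lower. None of these lists was called with an estimated correlation. Fry called the fatty acid (fry adjusted p = 0.00715), protein degradation (0.00277), cell cycle (0.00537), T and NK cell (0.00226) and B and plasma cell (0.00715) lists. It did not call the extracellular matrix list (0.0743), and it does not set a list against other genes. Pdk4 rose by 3.76 ± 0.76 log2 units (13.5-fold, n = 4 and 4, adjusted p = 0.00416), from 3.79 ± 0.71 (SD) in old controls to 7.55 ± 1.64 (SD). Ucp3, a mitochondrial carrier induced by fatty acids, rose by 3.14 ± 0.76 and Acot2, a mitochondrial thioesterase, by 2.92 ± 0.56. Of 32 fatty acid genes, 24 rose over all genes and 29 rose adjusted over the list alone, with a median of 0.67 (adjusted p = 0.426 with an estimated correlation). Of 30 protein degradation and autophagy genes, 27 rose over all genes and 28 rose adjusted over the list alone, with a median of 1.09 (camera adjusted p = 4.09e-09, adjusted p = 0.426 with an estimated correlation). These include Fbxo32 (2.96 ± 0.62, 7.77-fold), Cebpd, a stress-induced transcription factor (2.99 ± 0.75), Klf15, a glucocorticoid-responsive transcription factor (1.78 ± 0.37), and Sqstm1, an autophagy receptor (1.24 ± 0.25). Ddit4, an inhibitor of mTORC1 signalling, rose by 3.09 ± 0.77, Chac1, which degrades glutathione, by 3.09 ± 0.71, and the clock gene Per1 by 1.74 ± 0.36. Ppargc1a differed by 0.02 ± 0.20 (adjusted p = 0.945).

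The rises were uneven between the old MICT mice. Ddit4 was 8.54 and 8.57 in old MICT 1 and 2, 3.73 and 4.93 in old MICT 3 and 4, and 3.09 to 3.65 in old controls. Fbxo32 was 7.29 and 6.73 in old MICT 1 and 2, 4.85 and 4.43 in old MICT 3 and 4, and 2.64 to 3.12 in old controls, and Pdk4 was above every old control in all 4 old MICT mice.

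**Figure D2:**
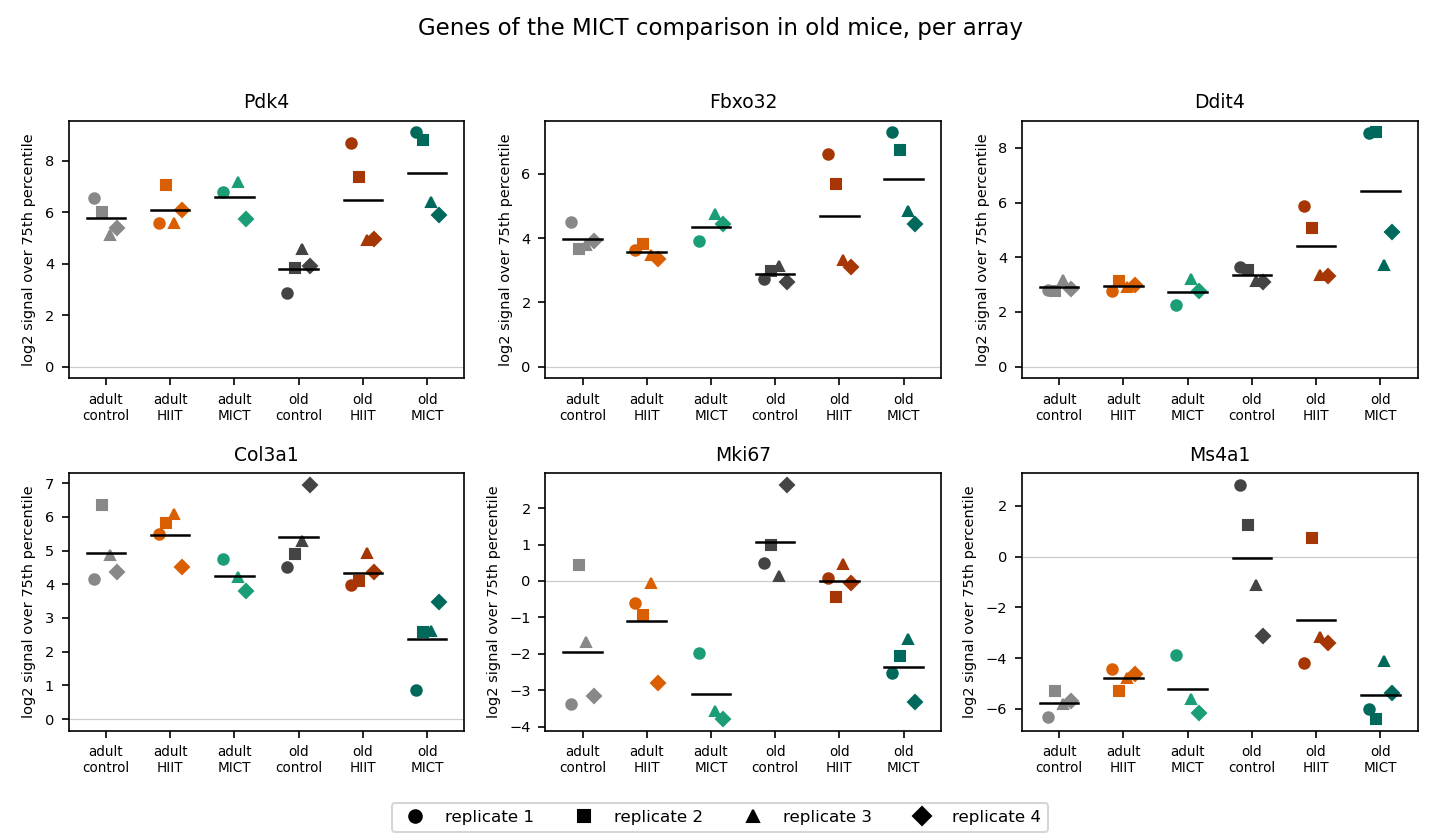
Scaled log2 signal of 6 genes per array (vertical axes), with arrays grouped by age and training, markers giving the replicate number and bars giving group means. Fbxo32 is 7.29 and 6.73 in old MICT 1 and 2 and 2.64 to 3.12 in the 4 old controls.

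Mitochondrial genes also rose with MICT in old mice. Of 72 respiratory chain and ATP synthase genes, 41 rose over all genes and 61 rose adjusted over the list alone, with a median of 0.39 against 0.19 for all genes (adjusted p = 0.457 with an estimated correlation). Ndufa7 rose by 0.36 ± 0.09. Of 20 tricarboxylic acid cycle genes, 15 rose over all genes and 19 rose adjusted over the list alone (adjusted p = 0.426 with an estimated correlation), among them Pdha1, the catalytic subunit of pyruvate dehydrogenase (0.58 ± 0.14). Slc2a4, the insulin-responsive glucose transporter, rose by 0.42 ± 0.13, and Mstn, which encodes the growth inhibitor myostatin, by 1.39 ± 0.44. Prdx3, a mitochondrial peroxidase, rose by 0.44 ± 0.10. The old controls with low respiratory chain scores were controls 1 and 2, which had the highest lymphocyte scores, and control 4, which had the highest neutrophil and mast cell score (5.50).

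Collagen and cell division genes were lower in old MICT than in old controls, which lie on another slide. Of 38 extracellular matrix genes, 16 fell and 1 rose over all genes, and 16 fell and 2 rose adjusted over the list alone (adjusted p = 0.426 with an estimated correlation). Col3a1 fell by 3.02 ± 0.55 and Col1a1 by 2.66 ± 0.57, the main fibrillar collagens of muscle connective tissue. Fibroblast markers, of which Col1a1, Dcn and Lum are also on the matrix list, moved with them: of 10, 6 fell and 1 rose over all genes, and 6 fell and 3 rose adjusted over the list alone, with a median of -0.72 (camera adjusted p = 0.0205, adjusted p = 0.426 with an estimated correlation). Of 19 cell cycle genes, 13 fell over all genes and 15 fell adjusted over the list alone, with a median of -2.19, or -1.63 with undetected genes at their bound (adjusted p = 0.373 with an estimated correlation). Mki67 fell by 3.44 ± 0.72 (10.8-fold). The cell cycle score was 3.78 in old control 4, which stood apart from the 1.07 to 1.23 of the other old controls. Of 8 B and plasma cell genes, 6 fell over all genes and 6 fell adjusted over the list alone, including Ms4a1, which fell by 5.42 ± 1.02 (adjusted p = 0.373 with an estimated correlation). Of 11 T and NK cell genes, 7 fell over all genes and 7 fell adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). Lymph node stroma genes, the list made after the rises with age were seen, moved with the lymphocyte genes. The log2 change was -4 in Glycam1 (limma adjusted p = 0.0115), -2.56 in Tnfsf11 (adjusted p = 0.00959) and -1.7 in Ccl19 (adjusted p = 0.034). Madcam1 changed by -0.36 (adjusted p = 0.531). Cx3cr1, a chemokine receptor of macrophages, fell by 3.07 ± 0.68. Old MICT had B and plasma cell scores of 0.12 to 1.17, against 5.56, 4.00, 1.88 and 1.40 in old controls 1, 2, 3 and 4, so controls 1 and 2 carry most of that difference. Extracellular matrix scores were -0.85, -0.78, -0.57 and -0.52 in old MICT 1, 2, 3 and 4. In old controls 1, 2, 3 and 4 they were -0.46, -0.20, -0.12 and 0.76. A change with training was not told apart from non-muscle tissue in the old controls here.

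For MICT in old mice limma called 7165 of 23708 features, 5025 higher and 2140 lower, so 70.1% were higher. The share was 56.5% with quantile scaling (3084 higher, 2374 lower) and 55.0% with z-scored arrays (2805 and 2292), and the median change of all genes went from 0.19 to 0.06 with quantile scaling. The groups did not overlap for 22.2% of features, where chance gives 2.86% on average over splits. Features are not independent, and how far this share varies between splits was not computed. Fitting only these groups, which lie on different slides, called 0 features; composition covariates called 4 (1 higher and 3 lower), of which 2 were among the 7165, and the arrays without old controls 1 and 2 called 398 (174 higher and 224 lower), of which 361 were, so the majority of higher features was lost in both. Leaving out single arrays gave 4376 (old control 1), 3701 (old control 2), 4107 (old MICT 1) and 4254 (old MICT 2).

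The regimens were compared directly at each age. In old mice, on 1 slide, Col3a1 was 1.97 ± 0.55 higher in HIIT than in MICT (n = 4 and 4, adjusted p = 0.209), Mki67 2.39 ± 0.72 higher (adjusted p = 0.209), and Klf15 differed by -1.20 ± 0.37 (adjusted p = 0.209). The 30 protein degradation genes were all negative, with a median of -0.56 (camera adjusted p = 1.99e-08, adjusted p = 0.474 with an estimated correlation). Schwann cell and nerve genes were all positive in the 11 measured, with a median of 0.77 (adjusted p = 0.474 with an estimated correlation). Cell cycle, T and NK cell and B and plasma cell genes moved with them, with medians of 1.17 over 19, 1.35 over 11 and 1.69 over 8 genes; 0 were called over all genes, and 9, 3 and 3 were higher adjusted over the list alone (adjusted p = 0.474 with an estimated correlation for each). The B and plasma cell score was 4.15 in old HIIT 2 and 0.90 to 1.37 in the other old HIIT arrays. In adult mice, where HIIT and MICT lie on different slides, the 16 slow-twitch genes were all positive, with 0 called over all genes, 14 higher adjusted over the list alone and a median of 1.69 (camera adjusted p = 7.82e-13, adjusted p = 0.859 with an estimated correlation), and Tnni1 differed by 2.68 ± 0.96 (n = 4 and 3, adjusted p = 0.511). Limma called 0 features in either age, with 4045 (old) and 1821 (adult) at an unadjusted p under 0.05 and smallest adjusted p values of 0.055 and 0.241. Array weights gave 3271 calls in adult mice, and 2 (without old HIIT 2), 1 (without old HIIT 3), 1 (without old HIIT 4), 1 (without old MICT 4) and 1 (without old control 4) features were called in old mice. Camera called 11 lists in adult mice, 17 without adult MICT 1 and 5 without adult MICT 3; fry called 0 lists at either age.

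The difference in response between ages was tested as an interaction. The groups of either interaction lie on all 3 slides, so a difference in response between ages cannot be told apart from slide. For MICT, Krt82 had an interaction (old minus adult) of 3.23 ± 0.56 (adjusted p = 0.0186), Gpr15 of 2.79 ± 0.52, and Gzmb of -3.61 ± 0.71 (adjusted p = 0.0315). Krt82 and Gpr15 were above background on no old control array, and Gzmb on no adult control, adult MICT or old MICT array, so these values rest partly on signal below background and carry no bound. Of the 158 features called, 51 had such a group. Phgdh had an interaction of -2.48 ± 0.54 (adjusted p = 0.0409), Myb, a transcription factor of blood precursors, of -4.11 ± 0.80, and H2-Eb2, an antigen presentation gene, of -4.50 ± 0.93. Klf15 had an interaction of 2.01 ± 0.54 (adjusted p = 0.0736) and Ms4a1 of -5.99 ± 1.5 (adjusted p = 0.0617), so neither passed. Of 30 protein degradation genes, 0 were called over all genes and 22 were higher adjusted over the list alone (median 1.00, adjusted p = 0.559 with an estimated correlation). Limma called 158 features for MICT, 138 higher and 20 lower in old mice, and 0 for HIIT, with 2698 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0685. For HIIT, array weights gave 5 calls and leaving out old HIIT 2 gave 3, and Gzmb had an interaction of -3.42 ± 0.69 (adjusted p = 0.179). For MICT, normexp background gave 0 calls, only the compared groups 1, composition covariates 1, and the arrays without old controls 1 and 2 22, and quantile scaling moved the median of all genes from 0.21 to 0.06. Leaving out single arrays gave 39, 24, 2045 and 75 (old controls 1, 2, 3 and 4), 20, 15, 433 and 35 (old MICT 1, 2, 3 and 4), 14, 621, 26 and 41 (adult controls 1, 2, 3 and 4), 81 (adult MICT 1), 21 (adult MICT 3), 81 (old HIIT 3), and 83, 260 and 66 (adult HIIT 2, 3 and 4). The HIIT arrays enter this test only through the pooled spread.

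Responses measured against the same controls were set beside simulated values. The draws took residuals from any of the 23 arrays, not from the shared controls alone. Old controls varied more than adult controls in some scores (B and plasma cell SD 1.93 against 0.13). The simulated covariances may therefore understate what sharing the old controls gives. Across genes, which are not independent replicates, the HIIT and MICT responses of old mice correlated at r = 0.657, which lies within the 0.004 to 0.730 (95% of draws, mean 0.467) of unchanged groups against shared controls. With the controls split between the comparisons r was 0.329, and the covariance was 0.26 against a simulated 0.0696 (0.0005 to 0.151). Of the features higher in old HIIT, 99 were also higher in old MICT, where independent lists would share 21.4 and unchanged groups shared 0 in every draw. The age difference and the old HIIT response correlated at r = -0.565 (simulated -0.5, from -0.782 to -0.076), and at -0.253 with split controls. Features lower with age and higher after HIIT numbered 83, where independent lists would share 9.16. The age difference and the old MICT response correlated at r = -0.797 (simulated -0.462, from -0.771 to 0.080; split controls -0.551), with a covariance of -0.491 against -0.0661 (-0.144 to 0.012). Features higher with age and lower after MICT numbered 781, where independent lists would share 97.9, and those lower with age and higher after MICT numbered 1443 against 455.7, with 0 of either kind in the simulated draws. Each draw was fitted with the groups of both its comparisons, and the real overlaps come from fits of all 23 arrays. Real fits of only the groups of a single comparison called 0 features for old HIIT, 0 for old MICT and 40 for age. The 0 shared in the draws is therefore not a like reference. The old controls enter both comparisons, which the independent lists leave out, and the draws leave out the effects, so the excess over neither measures a shared response. In adult mice the HIIT and MICT responses correlated at r = 0.177 (simulated 0.406, from -0.104 to 0.718), and at -0.0883 with split controls.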

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

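The tests of skin, of slide 2 as a source of lymphocyte genes, of dilution and of slide position, and the splits of samples for gene counts, were chosen only after the results were seen, as were the composition covariates and the sets of arrays left out; the criterion for skin was also reset after its values were seen. For slide 2 against the other slides the bound of -0.3 was set before, but the demand that the whole interval lie above it was added after the value was seen. In 580 groups of 4 arrays, 37 single arrays stood apart from the rest of their group by a gap above Dixon's 95% critical value. Chance alone marks about 1 in 20 groups.

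Lymphocyte genes were higher in old controls, most in old controls 1 and 2. Against slide 2, adult MICT on the same slide differed from adult controls by a B and plasma cell median of -0.13, where the old controls differed by 3.15. Against skin, 3 of the 5 arrays with keratinocyte scores over 5 had lymphocyte scores under 1, although keratinocyte scores reached 8.04 in old control 2. Lymph node stroma genes, of which 4 of 6 were measured and 1 was well above background in adult controls, had a median of 2.45 (exact permutation p = 0.0286, 2-sided). A 95% bootstrap interval over these genes, not over mice, ran from 0.60 to 4.58, the values of the lowest and highest gene. Ccl19, a chemokine of lymph node stroma, stood at 2.27, so some lymph node tissue beside the muscle is a candidate explanation. An effect of age on lymphocytes within the muscle was not tested and stays open.

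Fbxo32 and other atrophy genes were higher in old MICT. Against dilution of muscle RNA in old controls, fast-twitch genes had an upper quartile of 0.67 where Fbxo32 rose by 2.96, with a lower bound of 1.71. Against array position as a common effect, positions 1 and 2 differed from 3 and 4 by -0.04 on average in the 4 groups on slides 1 and 2. The range of 2 SE over these groups was -0.49 to 0.41. The difference was 2.93 in old HIIT and 2.37 in old MICT, so an effect of slide 3 alone cannot be excluded. Glucocorticoid-induced genes had a median of 1.22 in old MICT (exact permutation p = 0.0571, 2-sided), 8 of 11 of them called higher, with scores of 1.69 and 2.17 in old MICT 1 and 2 but -0.02 and 0.20 in old MICT 3 and 4; a stress hormone response may contribute, but the test leaves it open. Training itself stays open, and slide 3 against slide 2 cannot be told apart from it.

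Weakly expressed features were higher in old HIIT than in old controls. Of the 101 risers, 83 were also called lower in old than in adult controls. The old controls enter both comparisons, so a low signal in these controls stays open. Against lymphocyte and adipocyte RNA in the old controls as the whole cause, their median rise was 1.32 with composition covariates and 1.37 without. With the covariates 12 of the calls were kept. The median SE went from 0.27 to 0.30, and the cause of the loss of calls was not tested. Neutrophil and mast cell, macrophage and keratinocyte scores were not among the covariates, and the features were picked by their rise in these arrays. Other non-muscle RNA therefore stays open. Among features well above background on all arrays, 13 were called, compared with 103 in all. Of the 101 risers, 76 were not well above background on every old control array and could not enter that count, so the test decides nothing and noise near background stays open. The same features changed by a median of -0.29 in adult MICT on slide 2 against adult controls on slide 1. A 95% bootstrap interval over these features, which leaves out the spread between mice, was -0.35 to -0.24. This is the direction that a lower signal on slide 2 would give but far less than the rise, so slide and training cannot be told apart here. HIIT itself stays open and was not tested apart from slide.

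Other splits of the same arrays were fitted in the same way. For old MICT, 1 of 35 splits called as many features, the real one (7165, highest other 3344), which passes the rule of 1 in 20 but excludes chance only weakly. That share is the smallest that 35 splits allow, and it was not adjusted for the other comparisons. Nor does it tell training from slide or from the cell composition of the old controls. For age, 2 of 35 splits called as many (3235, highest other 4453) and for old HIIT 4 of 35 (103, highest other 829), so chance is not excluded there. For the MICT interaction, 2 of 100 splits called as many (158, highest other 2555), but these splits cannot exclude chance for an interaction. They shuffled the training labels within each age, so they stand for no training effect at either age, not for an equal response. All splits but the real one also counted old control 1 as MICT. Leaving out single arrays gave 14 to 2045. Splits calling several times the real count, here and in old HIIT, may point to a structure of the samples, whose cause was not tested. With 0 real calls, every split was as large: 35 of 35 in adult HIIT (highest other 19), adult MICT (0), HIIT against MICT in adult mice (65) and in old mice (1638), and 100 of 100 for the HIIT interaction (776). For lists, 1 of 35 splits called as many in old MICT (22, highest other 21), which excludes chance by the same rule, but by a single list, and leaving out single arrays gave 19 to 22. It is not excluded for adult HIIT (10 of 35 splits, 13 lists, highest other 17), adult MICT (31, 6 lists, 19), old HIIT (17, 15 lists, 20), age (17, 15 lists, 21), HIIT against MICT in adult mice (16, 11 lists, 19) and in old mice (5, 16 lists, 20), the HIIT interaction (56 of 100, 13 lists, 21) and the MICT interaction (10 of 100, 21 lists, 24). The other splits called a median of 9 to 14 lists, so camera at its preset correlation often calls many lists in other groupings of these arrays.

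Arrays with a list score apart from the other 3 of their group were old control 4 for cell cycle (3.78, others 1.07 to 1.23), old HIIT 2 for B and plasma cells (4.15, others 0.90 to 1.37) and old MICT 4 for mitochondrial biogenesis (0.12, others 0.16). Adult control 2 stood apart for angiogenesis (0.17), senescence (0.64) and the circadian clock (-0.31), adult control 1 for lipid synthesis (0.21), and adult HIIT 2 (-0.45) and old HIIT 2 (-0.20) for the circadian clock. The 75th percentile of the signal was 656 in adult HIIT 3, where the others had 403.1 to 434.6, and 655.2 in old HIIT 2.

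Single genes apart in old mice, as scaled log2 signal, were Spib in old MICT 4 (-4.90), Lce1a1 (-0.79) and Spock2 (0.96) in old MICT 2, Mylpf (3.68) and Sqstm1 (3.13) in old control 3, and Zim3 in old control 4 (-5.56). In old HIIT they were Pou2af1 (0.30), Top2a (-4.74) and Prdx3 (4.96) in array 2, Adipoq (1.5) and Zim3 (-1.84) in array 1, and Cyp2c67 in array 4 (-1.39). In adult HIIT, Lep (-0.86), Speer4c (-4.13), Zim3 (-2.74) and Ifi27l2a (6.58) stood apart in array 3, Top2a (-6.24) and Nsg2 (-4.48) in array 4, Mylpf (4.12) in array 1 and Csrp3 (7.83) in array 2. In adult controls, Adipoq (0.97), Mbp (0.64) and Cx3cr1 (1.26) stood apart in array 2, Alas2 (0.97) and Ddit4 (3.18) in array 3, and Depp1 (1.2) in array 1.

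The MICT interaction was called for 158 features in limma. Its groups lie on 3 slides, so slide and an age difference in response cannot be told apart. The named ones are Krt82 (3.23), Gpr15 (2.79), Olfr100 (2.76), Zim3 (2.76), Cyp2c67 (2.72), H2-Eb2 (-4.50), Nsg2 (-4.13), Syt13 (-4.13), Myb (-4.11), Gzmb (-3.61) and Phgdh (-2.48). No old control array had Krt82, Gpr15, Olfr100 or Cyp2c67 above background, and no old MICT array had Gzmb, Nsg2 or Syt13, so these values rest partly on signal below background.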

How the results depend on the processing

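Composition covariates, the sets of arrays left out and the exact test of list scores were chosen after the data were seen; the other settings were planned. Over pairs of a comparison and a setting, counts of called features kept within 1.5 times the main count in 147 and moved further in 82. A count of 0 that stayed 0 is among the 147. This was so in adult HIIT, adult MICT and HIIT against MICT in adult mice with each array left out. The 147 therefore do not show that counts above 0 were stable. Of 17923 values of named genes, each of 1 gene in 1 comparison under 1 setting, 15890 kept their side of the threshold. Another 1714 lost it, 303 gained it and 16 reversed. Where no cause is named below, the cause was not tested.

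For old HIIT (103 features), normexp background gave 0, quantile scaling 64, z-scored arrays 39, features well above background on all arrays 13, no intensity trend 225, only the groups compared 0, array weights 163, all probes 161, 393 from the value table, composition covariates 13, without old controls 1 and 2 12, and without old control 4 and old HIIT 1 5. For old MICT (7165), normexp gave 4117, only the groups compared 0, 4107 from the value table, composition covariates 4, without old controls 1 and 2 398, and a fold of at least 1.5 4774. For age (3235), normexp gave 2028, only the groups compared 40, array weights 7655, composition covariates 15, and without old controls 1 and 2 24. For the MICT interaction (158), normexp gave 0, quantile scaling 249, no filter 44, features well above background on all arrays 1, no intensity trend 279, only the groups compared 1, array weights 2467, all probes 242, composition covariates 1, and without old controls 1 and 2 22. Where the main count was 0, array weights gave 248 in adult HIIT, 2 in adult MICT, 3271 for HIIT against MICT in adult mice and 5 for the HIIT interaction. Quantile scaling and the value table gave 1 each for HIIT against MICT in old mice. For the HIIT interaction, no intensity trend gave 2, 8 from the value table, and without old controls 1 and 2 gave 1. Fits of the compared groups alone have fewer arrays to estimate the spread, and the stricter filter tests fewer features.

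In the additive model with slide, 0 features were called for old HIIT, 0 for old MICT and 0 for age; without slide it called 0 for HIIT, 0 for MICT and 2243 for age. With slide it has 6 terms for 6 groups. Its HIIT effect is then the adult difference on slide 1, its HIIT minus MICT effect is the old difference on slide 3, and its MICT and age effects are sums of differences from several slides. Its values therefore hold no information on how stable old HIIT is, or HIIT against MICT in adult mice. In it Olfr123 (-0.08), Krt82 (-0.60), Tcl1b2 (-0.02), Cyp4a12b (-0.48) and Gzmb (0.79) had the adult sign, opposite to old HIIT, and the sign also reversed in Phkb (-0.02), Actn3 (-0.06) and Gzmb (0.02) for old MICT and Eci1 (0.04) for age. With composition covariates Ccl5 (0.11), Derl3 (0.15), Cma1 (0.08) and Tpsb2 (0.02) reversed for old MICT, and H2-K1 (-0.04) and Ifi27l2a (-0.13) for age; with the value table, Gpx4 (0.03) reversed for age. Slide as a random block could not be estimated beside 6 group means and was not run; beside an additive model its correlation was 0.147.

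Leaving out each array in turn gave ranges of 0 to 0 for adult HIIT and adult MICT, 11 to 833 for old HIIT, 3701 to 8779 for old MICT, 510 to 5803 for age, 0 to 0 for HIIT against MICT in adult mice, 0 to 2 in old mice, 0 to 3 for the HIIT interaction and 14 to 2045 for the MICT interaction. Counts of lists ranged from 8 to 19 in adult HIIT, 3 to 12 in adult MICT, 12 to 18 in old HIIT, 19 to 22 in old MICT, 14 to 17 for age, 5 to 17 and 13 to 21 for HIIT against MICT in adult and old mice, and 12 to 18 and 17 to 21 for the HIIT and MICT interactions.

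With an estimated correlation, camera called 0 lists in each of the 9 comparisons, and limma's fry called 12 in old MICT, 9 for age and 0 elsewhere. The exact permutation of list scores, added later, called 0 lists after adjustment in each comparison of 2 groups; its smallest p of 0.0286 passes over 32 lists only if most lists reach it, so this count says little about stability. The additive model with slide called 12 lists for its MICT effect, which is the same for both ages. The model therefore does not show how stable the lists of adult MICT (6 in the main test) or old MICT (22) are. In it the extracellular matrix (adjusted p = 0.000754), lipid synthesis (0.00243) and adipocyte (0.000112) lists reversed for old HIIT, with the values of adult HIIT, and the respiratory chain (0.00264), tricarboxylic acid cycle (0.0178) and heat shock (0.0188) lists reversed for HIIT against MICT in adult mice, with the values of old mice. Correlations with controls split between comparisons were -0.0883 for adult HIIT and MICT, which reversed, 0.329 for old HIIT and MICT, -0.253 for age and old HIIT and -0.551 for age and old MICT.

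Replicate numbers share only the position on the slide. In no pair of groups did every same-numbered pair of arrays correlate over 0.1, and 7 of 23 arrays were closest to their own number. With the replicate block the HIIT interaction had 1 called feature instead of 0, and no other count of features or lists moved by over 1.5 times. Signal near background limits what can be said of features as weak as those called in old HIIT.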

Other observations

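The 32 lists were fixed before the data were examined, and keratinocyte scores per array were examined after the results were seen. In old MICT, 13 of 30 glycolysis and glycogen genes rose over all genes and 14 rose adjusted over the list alone (camera adjusted p = 0.00247, adjusted p = 0.457 with an estimated correlation). Of 25 antioxidant genes, 11 rose over all genes and 15 rose adjusted over the list alone (adjusted p = 0.426 with an estimated correlation). Of 23 genes of mitochondrial biogenesis and dynamics, 14 rose over all genes, and 15 rose and 1 fell adjusted over the list alone (adjusted p = 0.426 with an estimated correlation). Of 34 interferon and antigen presentation genes, 7 fell over all genes and 7 fell adjusted over the list alone (adjusted p = 0.426 with an estimated correlation). Of 21 lipid synthesis genes, 8 fell and 2 rose over all genes and adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). Depp1, a target of FOXO transcription factors, rose by 3.93 ± 0.89 (n = 4 and 4, limma adjusted p = 0.00604). Herpud1, a component of protein disposal from the endoplasmic reticulum, rose by 1.13 ± 0.22, Bag3, a co-chaperone of muscle, by 0.86 ± 0.19, and Arntl, a core clock gene, by 1.65 ± 0.40. Marco, a macrophage scavenger receptor, fell by 5.12 ± 0.99 in old MICT and rose by 5.96 ± 0.99 with age, with the highest lymphocyte scores in old controls 1 and 2.

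With age, Mbp, a myelin protein, rose by 1.23 ± 0.23 (n = 4 and 4, limma adjusted p = 0.00665) and Bglap2, which encodes the bone protein osteocalcin, rose by 5.48 ± 1.34, at least 11.1-fold, with an SD of 4.04 among old controls. Alas2, the first enzyme of heme synthesis in red cells, fell by 0.64 ± 0.20, and 1 of 8 red blood cell genes fell over all genes and adjusted over the list alone (adjusted p = 0.738 with an estimated correlation). Chrna9, an acetylcholine receptor subunit, rose by 2.24 ± 0.57 with age, at least 1.92-fold. Keratinocyte scores were 8.04 and 4.07 in old controls 2 and 3, 5.07, 5.99 and 7.61 in old HIIT 2, 3 and 4, and 6.48 and 2.65 in adult HIIT 3 and 4.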
